A study of Homo sapiens with 16 samples.

How the data were processed

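RNA of 16 libraries of 8505c cells was sequenced as paired-end reads from poly(A)-selected RNA with a strand-marking kit, per the labels' protocols. The libraries fall into 4 groups of 4 by the sample titles: shCtrl vehicle, shCtrl dabrafenib, shTAZ vehicle and shTAZ dabrafenib. The deposited table holds expected counts per gene, which the authors made with cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.0 on hg38, per the submitters' processing notes. The annotation release and whether the counting used the strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Genes with close paralogues, such as ALPP and AKR1C1, AKR1C2 and AKR1C3, are uncertain because expected counts split shared reads. Coordinates were taken from GENCODE release 29 for hg38, which is not stated to be the authors' annotation.

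The table has 61906 genes and 50498973 to 66669751 expected counts per library; 11.2% of values were not whole. They were rounded to whole numbers for the count tests. Genes were filtered with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which kept 18392. Counts were normalised by TMM in edgeR 4.0.16 on R 4.3.3, and CPM are normalised by these factors. All 16 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest) with 1 coefficient per group and no covariate. The 5 contrasts were the dabrafenib effect in each hairpin line, the shTAZ effect in each treatment, and the difference between the dabrafenib effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested.

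For 35 gene lists fixed before the data were examined, camera of limma 3.58.1 compared each list with the other genes, with a preset correlation of 0.01 and adjustment over all 175 tests; camera with an estimated correlation and fry were alternatives. With an estimated correlation camera called ERK readouts, stress response, glycolysis and hypoxia, and matrix proteases in shCtrl cells under dabrafenib; stress response, YAP/TAZ targets, glycolysis and hypoxia, matrix proteases, p53 targets and leukocyte markers in shTAZ cells; YAP/TAZ targets, stress response and receptor tyrosine kinases for the hairpin in vehicle; cholesterol synthesis for the hairpin under dabrafenib; and stress response for the difference. Of p53 targets 11 of 26 rose and 3 fell (11 and 3 adjusted over the list alone) in shTAZ cells with dabrafenib, and of leukocyte markers 3 of 3 fell and 0 rose (3 and 0 adjusted over the list alone). Genes to name were chosen by a rule written before the data were examined: WWTR1, TAFAZZIN and YAP1 always; the 8 largest called changes per direction among genes with average log2 CPM of at least 3 and, except for the difference, no overlap between groups; and up to 5 members of each described list with the smallest adjusted p. The genes of the largest changes are all named. Which lists to describe, and which of the 5 members to name, was chosen after their values were seen, mostly members whose call held with each library left out.

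The edgeR step was tested on simulated data with 200 changed genes and a planted list of 25 further genes at 1.50-fold, over 18114 genes. For the dabrafenib effect in shCtrl cells it recovered 55 of 67 at 1.50-fold, 66 of 67 at 2-fold, 65 of 66 at 4-fold, with 219 calls, of which 20 were members of the planted list and 13 were false. For the difference it recovered 42 of 67 at 1.50-fold, 56 of 67 at 2-fold, 64 of 66 at 4-fold, with 181 calls, of which 14 were members of the planted list and 5 were false, and for the dabrafenib effect in shTAZ cells, where nothing was changed, it made 0 calls. The planted list gave a camera p of 3.72e-49 and an unchanged list 0.637. Simulated genes were drawn independently, so this does not test whether the preset correlation is high enough. Far fewer genes were changed than were called in the data. Replicates differed by more than counting noise, with a chi-square per gene of 4.16 to 259.8 over 24 replicate pairs.

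Alternatives were size factors of DESeq2 1.42.0, DESeq2's Wald test, no filter and a stricter filter (CPM of at least 1 in 4 libraries), unrounded values, only the groups compared, a replicate block, and leaving out each library in turn. A covariate of the log2 mitochondrial percent and the removal of mitochondrial genes were added after seeing the data. Two-sided exact permutation tests compared the mitochondrial share between groups.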

Results

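Poly(A) RNA was sequenced from 8505c cells, a human cell line derived from an anaplastic thyroid carcinoma, an undifferentiated and aggressive thyroid cancer. The cells carried a control hairpin (shCtrl) or a hairpin named for TAZ (shTAZ), and received vehicle or dabrafenib, an inhibitor of the BRAF kinase. Each of the 4 groups had 4 libraries, so 16 were compared, with 50498973 to 66669751 expected counts per library. The series title names resistance of anaplastic thyroid cancer to BRAF inhibition, and the groups allow the dabrafenib response to be compared between the hairpins. Dose and duration were not stated. The sample titles name only shCtrl and shTAZ, with no further hairpin or line against TAZ. Any other difference between these cells therefore cannot be told apart from an effect of lower TAZ. The shTAZ effect below means the difference between shTAZ and shCtrl cells. The replicates are not stated to be separate cultures, so the p-values measure only the spread between these samples, which may be technical. Changes are given as log2 fold changes ± standard error from edgeR's quasi-likelihood fit with 4 libraries per group. A gene is said to rise or fall where its Benjamini-Hochberg adjusted p was under 0.05.

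TAZ is the protein of WWTR1, a transcriptional co-activator of the Hippo pathway and paralogue of YAP1, and TAZ was also an earlier symbol of TAFAZZIN, a mitochondrial cardiolipin enzyme. WWTR1 lies on chromosome 3 at 149517235 to 149736714 on the minus strand of hg38. Its level in the 4 shCtrl vehicle libraries was 135, 151, 147 and 152 CPM, and in the 4 shTAZ vehicle libraries 84.6, 72.6, 64.3 and 81.5 CPM. Under dabrafenib it was 74.8, 75.3, 80.9 and 82.1 CPM in shCtrl and 51.3, 51.4, 50.001 and 46.1 CPM in shTAZ cells. The shTAZ cells thus held 51.9% of the control level in vehicle (log2 -0.95 ± 0.071, edgeR adjusted p = 3.47e-08) and 63.5% under dabrafenib (-0.66 ± 0.072, adjusted p = 2.14e-06). Dabrafenib itself lowered WWTR1 in shCtrl (-0.90 ± 0.071) and shTAZ cells (-0.61 ± 0.072), and the difference between these effects was not called (0.29 ± 0.10, edgeR adjusted p = 0.113).

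TAFAZZIN lies on chromosome X at 154411518 to 154421726 on the plus strand. Its CPM was 22.8, 23.8, 19.97 and 27.4 in shCtrl vehicle, 26.1, 27.3, 24.1 and 24.9 in shCtrl dabrafenib, 26.6, 22.4, 27.5 and 24.7 in shTAZ vehicle and 23.2, 24.7, 22.7 and 35.5 in shTAZ dabrafenib libraries, with no call in any of the 5 comparisons. YAP1, on chromosome 11 at 102110461 to 102233423 on the plus strand, had 248, 247, 265 and 249 CPM in shCtrl vehicle, 230.4, 233, 251 and 248 in shCtrl dabrafenib, 228, 225, 208 and 230.4 in shTAZ vehicle and 233, 224, 231 and 199 in shTAZ dabrafenib libraries. Its shTAZ effect in vehicle was -0.18 ± 0.052 (edgeR adjusted p = 0.0134); with the mitochondrial percent as a covariate, chosen after seeing the data, it was -0.13 and not called.

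**Figure D1:**
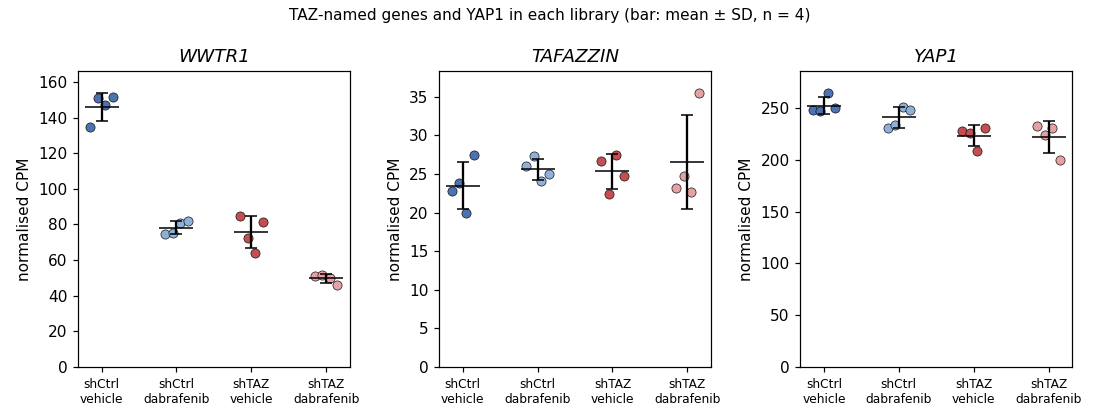
Normalised CPM of WWTR1, TAFAZZIN and YAP1 in each library (points), with the group mean and SD (bars, n = 4). All shTAZ libraries lie below the shCtrl libraries of the same treatment for WWTR1, whose group means were 146 ± 7.88, 78.3 ± 3.74, 75.7 ± 9.19 and 49.7 ± 2.49 CPM from left to right.

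The first comparison asked what dabrafenib changed in cells with the control hairpin. Most readouts of ERK signalling, inflammatory cytokines, hypoxia and glycolysis genes and secreted proteases fell, while most amino acid stress genes, YAP/TAZ target genes and antioxidant genes rose. Camera's calls were lost for the cytokines (adjusted p = 0.351 with an estimated correlation), the YAP/TAZ targets (0.0739) and the antioxidant genes (0.157). Of 18392 genes tested, 4039 rose and 3485 fell, 717 and 929 of them at least 2-fold. PAPPA2, a protease of insulin-like growth factor binding proteins, rose 51.0-fold (5.67 ± 0.18, edgeR adjusted p = 3.30e-13), from a mean of 0.413 to 21.2 CPM. IL33, an alarmin cytokine, fell 35.2-fold (-5.14 ± 0.50, edgeR adjusted p = 2.91e-07), from 4.47 to 0.126 CPM. The size of both folds rests on the low counts of 1 group. KCNK15, a potassium channel, rose (3.05 ± 0.12), as did ALPP, a placental alkaline phosphatase whose reads are shared with close paralogues (3.58 ± 0.22). TNFSF15, a TNF-family cytokine (-4.23 ± 0.25), CEMIP, which takes part in hyaluronan breakdown (-4.04 ± 0.39), STC1 (-3.97 ± 0.24) and RGS4, a regulator of G-protein signalling (-3.55 ± 0.18), fell. ADM2, a peptide hormone (2.79 ± 0.10), SEL1L3 (2.82 ± 0.15), the alpha kinase ALPK2 (2.67 ± 0.13) and the matricellular CCN5 (2.61 ± 0.16) were also among the largest rises.

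Among ERK pathway readouts, 18 of 20 fell and 2 rose (18 and 2 adjusted over the list alone; median log2 fold change -1.09). The list test (camera) had adjusted p = 8.94e-30, or adjusted p = 0.0413 with an estimated correlation. The ETS factors ETV1 (-2.95 ± 0.080), ETV4 (-2.73 ± 0.12) and ETV5 (-1.66 ± 0.072) and the phosphatase DUSP6, which acts on ERK (-3.37 ± 0.19), fell, and so did SPRED3 (-2.60 ± 0.14). In the list of the integrated stress response, the programme of ATF4 to amino acid shortage and other stresses, 29 of 30 rose and 0 fell (30 and 0 adjusted over the list alone; median log2 fold change 1.178). By camera the adjusted p was 5.47e-68, and adjusted p = 0.00116 with an estimated correlation. Its members included NUPR1 (2.40 ± 0.071), SESN2 (1.96 ± 0.060), the amino acid transporters SLC3A2 (1.48 ± 0.047), SLC7A5 (2.58 ± 0.10) and SLC1A4 (1.85 ± 0.078), and CHAC1, which degrades glutathione (2.59 ± 0.15). Among YAP/TAZ target genes, 15 of 21 rose and 1 fell (15 and 1 adjusted over the list alone; median log2 fold change 0.60). For the list, camera's adjusted p = 1.27e-06, against adjusted p = 0.0739 with an estimated correlation. ANKRD1 (2.21 ± 0.14), GADD45A (0.83 ± 0.050) and AMOTL2 (0.68 ± 0.056) rose while NT5E fell (-1.06 ± 0.065).

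Of the inflammatory cytokine list, which holds targets of NF-kB, 24 of 29 fell and 2 rose (24 and 2 adjusted over the list alone; median log2 fold change -2.03). Against other genes, camera gave adjusted p = 3.19e-10, and adjusted p = 0.351 with an estimated correlation. The chemokines CXCL8 (-3.69 ± 0.33), CXCL1 (-2.86 ± 0.28) and CCL2 (-2.40 ± 0.16) and the prostaglandin synthase PTGS2 (-2.36 ± 0.18) fell. In the glycolysis and hypoxia list, 25 of 31 fell and 2 rose (26 and 2 adjusted over the list alone; median log2 fold change -0.49). As a list, camera adjusted p = 2.13e-20 and adjusted p = 0.0256 with an estimated correlation. CA9, a carbonic anhydrase induced by hypoxia, fell 31.4-fold (-4.97 ± 0.15), and BNIP3 (-1.26 ± 0.042) and PFKFB3 (-1.18 ± 0.051) fell as well. In the list of matrix proteases and their regulators, 16 of 20 fell and 3 rose (16 and 3 adjusted over the list alone; median log2 fold change -0.76). Camera's adjusted p was 1.97e-13 with the preset correlation and adjusted p = 0.0413 with an estimated correlation. MMP3 (-3.05 ± 0.11), MMP1 (-2.68 ± 0.13) and PLAT (-1.54 ± 0.076) fell. Of mitotic genes, 28 of 33 fell and 0 rose (29 and 0 adjusted over the list alone; median log2 fold change -0.44). Under camera adjusted p = 3.51e-07 was found, with adjusted p = 0.578 with an estimated correlation. NRF2 and ferroptosis genes rose as a list, where 21 of 28 rose and 1 fell (21 and 1 adjusted over the list alone; median log2 fold change 0.33). Tested against other genes, the list had camera adjusted p = 1.11e-11, and adjusted p = 0.157 with an estimated correlation. NQO1 (1.35 ± 0.086) and AKR1C1, whose reads are shared with AKR1C2 and AKR1C3 (2.50 ± 0.15), were among them.

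Markers of endothelial cells also moved in this cell line, where 7 of 10 fell and 0 rose (7 and 0 adjusted over the list alone; median log2 fold change -1.35). In camera's comparison adjusted p = 1.05e-06, and adjusted p = 0.0632 with an estimated correlation. CDH5 (-1.79 ± 0.11), TIE1 (-2.27 ± 0.14) and ROBO4 (-3.61 ± 0.24) fell. The mitochondrial share of counts was 2.59 ± 2.22% (SD, n = 4) in shCtrl vehicle and 2.47 ± 1.07% in shCtrl dabrafenib libraries (two-sided exact permutation p = 0.914, 0.914 adjusted over 4 comparisons). Replicate 4 of shCtrl vehicle held 5.82%; without it 3338 genes rose and 3592 fell.

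The second comparison asked the same of cells with the TAZ hairpin. Among the groups that moved, most ERK readouts, cytokines, hypoxia genes and proteases fell again, and most stress and YAP/TAZ target genes rose. Camera's calls were lost for the ERK readouts (adjusted p = 0.153 with an estimated correlation) and the cytokines (0.182). Of 18392 genes, 3507 rose and 3443 fell, 603 and 773 at least 2-fold. PAPPA2 rose 38.8-fold (5.28 ± 0.16, edgeR adjusted p = 2.38e-13), from a mean of 0.955 to 37.4 CPM, and ADM2 rose 19.2-fold (4.26 ± 0.11). JDP2, a bZIP factor (3.41 ± 0.088), and CGA, the alpha subunit of glycoprotein hormones (2.96 ± 0.15), rose. The amino acid transporter SLC6A14 fell 18.4-fold (-4.20 ± 0.32), and IL33 (-4.13 ± 0.32), CEMIP (-3.45 ± 0.34) and TNFSF15 (-3.44 ± 0.24) fell. ALPP rose (2.92 ± 0.31), and the cytokines CXCL1 (-3.43 ± 0.27) and IL1B (-3.39 ± 0.38) fell.

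In shTAZ cells, of the integrated stress response list 30 of 30 rose and 0 fell (30 and 0 adjusted over the list alone; median log2 fold change 1.57). Camera gave adjusted p = 3.48e-133 for the list, and adjusted p = 1.05e-04 with an estimated correlation. The cystine transporter SLC7A11 (3.55 ± 0.13), CHAC1 (3.98 ± 0.16), SLC7A5 (3.05 ± 0.10) and STC2 (2.01 ± 0.060) were among the largest rises. Of ERK readouts 17 of 20 fell and 2 rose (17 and 2 adjusted over the list alone; median log2 fold change -0.80). The list test (camera) had adjusted p = 2.97e-15, or adjusted p = 0.153 with an estimated correlation. Examples were ETV1 (-1.84 ± 0.075), ETV4 (-1.94 ± 0.11) and DUSP6 (-2.51 ± 0.18). Of YAP/TAZ targets 18 of 21 rose and 1 fell (18 and 1 adjusted over the list alone; median log2 fold change 0.55). By camera the adjusted p was 2.65e-13, and adjusted p = 0.0287 with an estimated correlation. ANKRD1 (2.58 ± 0.14) and CCN1 (1.49 ± 0.090) rose. Of the cytokine list 26 of 29 fell and 1 rose (27 and 1 adjusted over the list alone; median log2 fold change -1.89). For the list, camera's adjusted p = 1.70e-18, against adjusted p = 0.182 with an estimated correlation. CXCL8 fell (-4.02 ± 0.32) and IL24 rose (1.47 ± 0.10). Hypoxia and glycolysis genes fell, where 27 of 31 fell and 1 rose (27 and 1 adjusted over the list alone; median log2 fold change -0.36). Against other genes, camera gave adjusted p = 2.17e-23, and adjusted p = 0.0159 with an estimated correlation. CA9 was -3.84 ± 0.14 and PFKFB4 -2.04 ± 0.10. Of matrix proteases 15 of 20 fell and 4 rose (15 and 4 adjusted over the list alone; median log2 fold change -0.75). As a list, camera adjusted p = 5.91e-11 and adjusted p = 0.0496 with an estimated correlation. MMP3 (-2.91 ± 0.10) and MMP10 (-2.32 ± 0.11) fell. Of mitotic genes 16 of 33 fell and 0 rose (21 and 0 adjusted over the list alone; median log2 fold change -0.25). Camera's adjusted p was 9.26e-04 with the preset correlation and adjusted p = 0.740 with an estimated correlation. CDC25B, a phosphatase of mitotic entry, fell (-0.46 ± 0.053). The number of mitotic genes that fell was 6 without shTAZ vehicle replicate 2, 8 without shTAZ vehicle replicate 3 and 10 without shTAZ dabrafenib replicate 2.

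Interferon-stimulated genes fell with dabrafenib in shTAZ cells, where 30 of 38 fell and 0 rose (32 and 0 adjusted over the list alone; median log2 fold change -0.76). Under camera adjusted p = 1.53e-06 was found, with adjusted p = 0.589 with an estimated correlation. Without shTAZ vehicle replicate 3, 20 fell and the median was -0.45. ISG20 (-1.40 ± 0.16) and IFITM1 (-1.05 ± 0.12) were among them. The falls of ISG20 and IFITM1 were not particular to shTAZ cells. From vehicle to dabrafenib in shCtrl cells, mean ISG20 went from 38.8 to 9.52 CPM and mean IFITM1 from 305 to 121 CPM. The interferon gene HERC5 was at 13.3 and 13.9 CPM there. Over the whole interferon list the dabrafenib effect was lower in shTAZ than in shCtrl cells (median difference -0.40). Camera called that difference with the preset correlation. The call was lost with an estimated correlation and without shTAZ vehicle replicate 3. Of antigen presentation genes 14 of 24 fell and 1 rose (16 and 1 adjusted over the list alone; median log2 fold change -0.35). Tested against other genes, the list had camera adjusted p = 6.04e-04, and adjusted p = 0.526 with an estimated correlation. HLA-B (-0.84 ± 0.10) and HLA-E (-0.54 ± 0.069) fell. Of NRF2 and ferroptosis genes 15 of 28 rose and 3 fell (16 and 3 adjusted over the list alone; median log2 fold change 0.21). In camera's comparison adjusted p = 3.51e-07, and adjusted p = 0.284 with an estimated correlation. Of endothelial markers 6 of 10 fell and 0 rose (6 and 0 adjusted over the list alone; median log2 fold change -1.18). Camera gave adjusted p = 1.06e-06 for the list, and adjusted p = 0.0632 with an estimated correlation. The mitochondrial share was 4.84 ± 1.84% (SD, n = 4) in shTAZ vehicle and 6.66 ± 4.79% in shTAZ dabrafenib libraries (two-sided exact permutation p = 0.686, 0.914 adjusted over 4 comparisons), and replicate 4 of the latter held 13.8%. Without that library 3675 genes rose and 3376 fell.

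Across the 18392 genes, the dabrafenib effects in the 2 hairpin lines had Pearson's r = 0.735 and Spearman's rho = 0.674; these are correlations across genes, which are not independent replicates, and the 2 effects share no library. With no filter on low counts r was 0.211, and with a stricter filter 0.851. In both lines 2649 genes rose and 2382 fell, against 770.2 and 652 for independent lists. Opposite calls were given to 64 genes, against 1421 for independent lists.

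**Figure D2:**
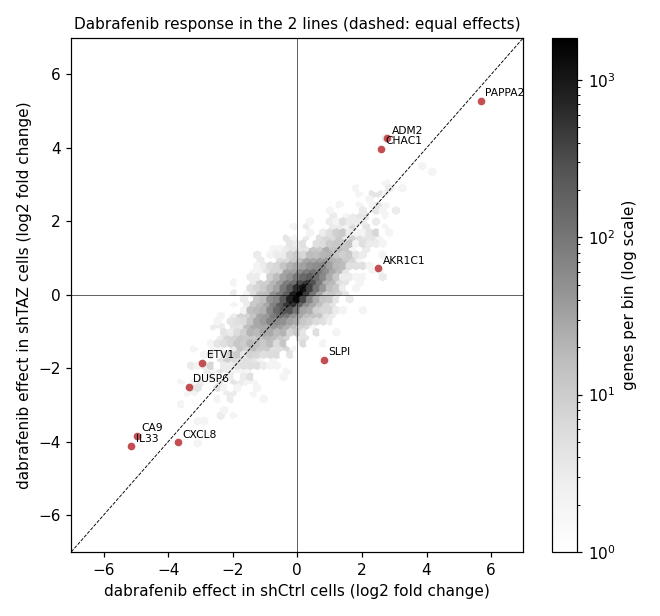
Dabrafenib effect in shTAZ cells (vertical axis, log2 fold change) against that in shCtrl cells (horizontal axis, log2 fold change) for the genes tested, binned by density on a log scale. The dashed line marks equal effects, and labelled genes such as CHAC1 (2.59 and 3.98) and AKR1C1 (2.50 and 0.72) lie away from it.

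**Figure D3:**
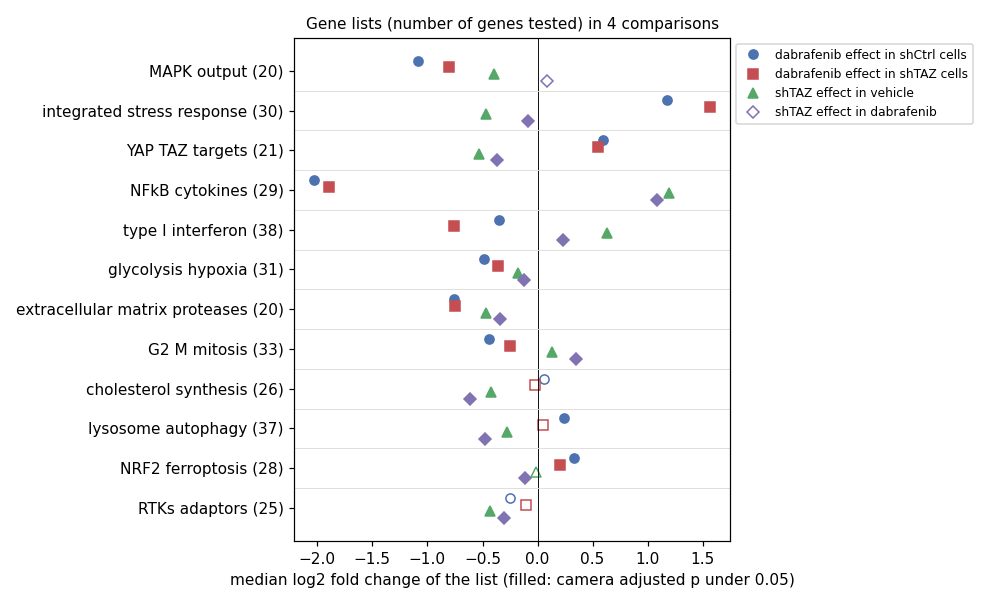
Median log2 fold change of 12 gene lists (horizontal axis) in the 2 dabrafenib and the 2 hairpin comparisons, with the number of genes tested in brackets. Filled symbols mark camera adjusted p under 0.05. The integrated stress response list lies at 1.178 and 1.57 for dabrafenib and at -0.47 for the hairpin in vehicle.

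The third comparison asked what differed between shTAZ and shCtrl cells in vehicle. Most YAP/TAZ targets, stress response genes, cholesterol synthesis genes and receptor tyrosine kinases were lower in shTAZ cells, and most inflammatory cytokine and interferon genes were higher. Camera's calls were lost for the cholesterol genes (adjusted p = 0.106 with an estimated correlation), the cytokines (0.275) and the interferon genes (0.622), and without shTAZ vehicle replicate 3 only 16 of 38 interferon genes were higher. Of 18392 genes, 2782 were higher and 3459 lower, 532 and 451 at least 2-fold. KYNU, kynureninase of tryptophan breakdown, was 12.4-fold higher (3.64 ± 0.23, edgeR adjusted p = 4.29e-09), and IL33 (3.52 ± 0.30), the protease inhibitor SLPI (3.43 ± 0.15) and complement C3 (2.35 ± 0.16) were higher. ALPP, with its paralogues, was 10.6-fold lower (-3.40 ± 0.30, edgeR adjusted p = 2.39e-07). The atypical cadherin FAT3 (-3.04 ± 0.19) and the matrix genes FBLN1 (-2.93 ± 0.11), NID2 (-2.08 ± 0.15) and MFAP5 (-2.01 ± 0.19) were lower. COL27A1 (2.38 ± 0.38), SLC6A14 (2.12 ± 0.28) and the chitinase-like CHI3L1 (2.12 ± 0.17) were higher, and NYNRIN (-2.14 ± 0.12) and the keratinocyte gene KPRP (-1.89 ± 0.13) lower.

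Of YAP/TAZ targets in vehicle 13 of 21 were lower and 1 was higher (13 and 1 adjusted over the list alone; median log2 fold change -0.53). The list test (camera) had adjusted p = 1.94e-11, or adjusted p = 0.0413 with an estimated correlation. The matricellular genes CCN1 (-1.33 ± 0.089) and CCN2 (-1.48 ± 0.12) and the genes AMOTL2 (-0.76 ± 0.056), GADD45A (-0.72 ± 0.051) and CRIM1 (-0.91 ± 0.074) were lower. Of the integrated stress response list 23 of 30 were lower and 0 were higher (24 and 0 adjusted over the list alone; median log2 fold change -0.47). By camera the adjusted p was 1.60e-22, and adjusted p = 0.0413 with an estimated correlation. VLDLR (-1.46 ± 0.057), STC2 (-1.40 ± 0.059) and SLC1A4 (-2.02 ± 0.086) were lower. Of cholesterol synthesis genes 21 of 26 were lower and 0 were higher (21 and 0 adjusted over the list alone; median log2 fold change -0.42). For the list, camera's adjusted p = 3.40e-15, against adjusted p = 0.106 with an estimated correlation. LSS (-0.54 ± 0.045), HMGCS1 (-0.73 ± 0.062) and SQLE (-0.84 ± 0.071) were lower. Of receptor tyrosine kinases and adaptors 18 of 25 were lower and 1 was higher (18 and 2 adjusted over the list alone; median log2 fold change -0.43). Against other genes, camera gave adjusted p = 4.94e-08, and adjusted p = 0.0448 with an estimated correlation. MERTK (-1.69 ± 0.12), ERBB3 (-1.08 ± 0.10) and INSR (-0.58 ± 0.064) were lower. Of ERK readouts 12 of 20 were lower and 0 were higher (13 and 0 adjusted over the list alone; median log2 fold change -0.40). As a list, camera adjusted p = 2.81e-05 and adjusted p = 0.480 with an estimated correlation. EPHA4 (-1.30 ± 0.086) and CCND1 (-0.86 ± 0.14) were lower.

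Of the cytokine list in vehicle 26 of 29 were higher and 2 were lower (26 and 2 adjusted over the list alone; median log2 fold change 1.19). Camera's adjusted p was 1.21e-12 with the preset correlation and adjusted p = 0.275 with an estimated correlation. IL6 (1.92 ± 0.20), CXCL1 (2.04 ± 0.25), SOD2 (1.53 ± 0.17) and CCL2 (1.23 ± 0.14) were higher and IL24 lower (-0.83 ± 0.10). Of interferon-stimulated genes 22 of 38 were higher and 1 was lower (27 and 2 adjusted over the list alone; median log2 fold change 0.63). Under camera adjusted p = 9.43e-06 was found, with adjusted p = 0.622 with an estimated correlation. IFI44 (1.97 ± 0.29), OAS2 (1.60 ± 0.27) and HERC5 (0.74 ± 0.10) were higher. Without shTAZ vehicle replicate 3, 16 interferon genes were higher and the median was 0.33. The mitochondrial share was 4.84 ± 1.84% in shTAZ vehicle against 2.59 ± 2.22% (SD, n = 4) in shCtrl vehicle libraries (two-sided exact permutation p = 0.200, 0.400 adjusted over 4 comparisons). The list of mitochondrially encoded transcripts had a median of 0.90 and no camera call (adjusted p = 0.0522). It was called without shCtrl vehicle replicate 4 (median 1.68, 10 members higher, adjusted p = 0.00123) and without shTAZ vehicle replicate 2 (adjusted p = 0.0108). With the log2 mitochondrial percent as a covariate, an alternative chosen after seeing the data, 20 cytokine genes and 16 interferon genes were higher. Without shCtrl vehicle replicate 4, 2864 genes were higher and 3365 lower over all genes.

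The fourth comparison asked what differed between shTAZ and shCtrl cells under dabrafenib. Most cholesterol synthesis, lysosomal and YAP/TAZ target genes were lower in shTAZ cells, and most cytokine and mitotic genes were higher. Of these, camera's call held for the cholesterol genes only; it was lost for the lysosomal genes (adjusted p = 0.0739 with an estimated correlation), the YAP/TAZ targets (0.146), the cytokines (0.526) and the mitotic genes (0.578). Of 18392 genes, 2854 were higher and 3739 lower, 675 and 461 at least 2-fold. IL33 was 23.1-fold higher (4.53 ± 0.53, edgeR adjusted p = 4.21e-06), and KYNU (3.43 ± 0.26), C3 (2.996 ± 0.17) and the interferon gene IFI44L (3.001 ± 0.50) were higher. Mean levels in shTAZ and shCtrl cells were 2.93 and 0.126 CPM for IL33 and 7.31 and 0.675 CPM for KYNU. The size of these folds rests on the low counts in shCtrl cells. ALPP was 16.6-fold lower (-4.06 ± 0.23), and the sulfatase SULF1 (-2.77 ± 0.14), FBLN1 (-2.59 ± 0.11), the integrin ITGB2 (-2.50 ± 0.11) and MFAP5 (-2.36 ± 0.18) were lower. CEMIP (2.23 ± 0.41) and the non-coding FENDRR (2.14 ± 0.11) were higher, and FAT3 (-2.46 ± 0.18), the bicarbonate transporter SLC4A4 (-2.16 ± 0.15) and the channel subunit KCNMB4 (-2.14 ± 0.13) lower. The collagen genes COL27A1 (3.54 ± 0.42) and COL7A1 (2.12 ± 0.36) were higher; they stood highest in shTAZ dabrafenib replicate 4, and with the mitochondrial covariate COL7A1 was at 1.21.

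Of cholesterol genes under dabrafenib 22 of 26 were lower and 0 were higher (23 and 0 adjusted over the list alone; median log2 fold change -0.61). Tested against other genes, the list had camera adjusted p = 2.17e-23, and adjusted p = 0.0448 with an estimated correlation. MSMO1 (-1.30 ± 0.083) and LSS (-0.71 ± 0.045) were lower, and so was the desaturase SCD (-1.56 ± 0.11). Of lysosome and autophagy genes 32 of 37 were lower and 2 were higher (33 and 2 adjusted over the list alone; median log2 fold change -0.48). In camera's comparison adjusted p = 2.94e-18, and adjusted p = 0.0739 with an estimated correlation. LAMP1 (-1.15 ± 0.066), ASAH1 (-1.07 ± 0.074) and MCOLN1 (-0.66 ± 0.054) were lower. Of YAP/TAZ targets 13 of 21 were lower and 0 were higher (13 and 1 adjusted over the list alone; median log2 fold change -0.37). Camera gave adjusted p = 2.20e-05 for the list, and adjusted p = 0.146 with an estimated correlation. AMOTL2 (-0.60 ± 0.055) and CCN1 (-0.66 ± 0.088) were lower. Of mitotic genes 25 of 33 were higher and 0 were lower (27 and 0 adjusted over the list alone; median log2 fold change 0.35). The list test (camera) had adjusted p = 4.81e-07, or adjusted p = 0.578 with an estimated correlation. PLK1 (0.57 ± 0.10) and AURKA (0.49 ± 0.10), kinases of mitosis, were higher. Of the cytokine list 18 of 29 were higher and 1 was lower (20 and 1 adjusted over the list alone; median log2 fold change 1.09). By camera the adjusted p was 4.52e-06, and adjusted p = 0.526 with an estimated correlation. IL11 (2.02 ± 0.27) and IL6 (1.14 ± 0.19) were higher. Of ERK readouts 5 of 20 were higher and 5 were lower (5 and 5 adjusted over the list alone) (camera adjusted p = 0.303); ETV1 was higher (1.06 ± 0.080) and EGR1 lower (-0.90 ± 0.16). Of the stress response list 10 of 30 were lower and 3 were higher (10 and 3 adjusted over the list alone; median log2 fold change -0.089). For the list, camera's adjusted p = 0.0106, against adjusted p = 0.589 with an estimated correlation. VLDLR (-1.15 ± 0.056) and SLC1A4 (-1.10 ± 0.076) were lower. Without shTAZ dabrafenib replicate 4 the median of the stress response list was -0.035.

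Of mitochondrially encoded transcripts 4 of 13 were higher and 0 were lower (11 and 0 adjusted over the list alone) in shTAZ than in shCtrl dabrafenib libraries (median log2 fold change 1.45). Against other genes, camera gave adjusted p = 0.0146, and adjusted p = 0.740 with an estimated correlation. Without shTAZ dabrafenib replicate 4 the camera call was lost (adjusted p = 0.102), the median was 0.78 and 0 members were called. Also 0 members were called without shCtrl dabrafenib replicate 1, 3 or 4 and with DESeq2, with medians of 1.20, 1.33, 1.56 and 1.47. The count was 8 without shCtrl dabrafenib replicate 2 or shTAZ dabrafenib replicate 1 or 3, 6 with DESeq2's size factors, 7 with a replicate block, 13 with no filter on low counts, 8 with a stricter filter and 10 with only the groups compared. The mitochondrial share was 6.66 ± 4.79% against 2.47 ± 1.07% (SD, n = 4), higher in all 4 shTAZ than in all 4 shCtrl libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow, and 0.114 adjusted over 4 comparisons). Without replicate 4, 2613 genes were higher and 2995 lower. Across genes the shTAZ effects in vehicle and dabrafenib, which share no library, had r = 0.636 and rho = 0.632 (r = 0.142 with no filter on low counts and 0.760 with a stricter filter); 1537 genes were higher and 2348 lower in both, and 112 had opposite calls.

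The last comparison tested whether the dabrafenib effect differed between the hairpins. Of stress response genes 16 of 30 rose more, and some ERK readouts fell less, in shTAZ than in shCtrl cells, while a minority of lysosomal and antioxidant genes had lower effects in shTAZ cells. Apart from the stress response, camera's calls were lost here, for the ERK readouts (adjusted p = 0.142 with an estimated correlation), the lysosomal genes (0.259) and the antioxidant genes (0.521). The difference was called for 921 of 18392 genes, 412 with a higher and 509 with a lower effect in shTAZ cells. By size of the log2 fold change, 590 of the 921 responded less and 331 more in shTAZ cells. The laminin gene LAMA4 (1.71 ± 0.15, edgeR adjusted p = 6.32e-06), the granin SCG2 (1.66 ± 0.20), the hedgehog inhibitor HHIP (1.53 ± 0.20), ADM2 (1.47 ± 0.15) and the transglutaminase TGM2 (1.24 ± 0.11) had higher effects. SLPI (-2.58 ± 0.21, edgeR adjusted p = 2.14e-06), FYB1 (-2.21 ± 0.29), the epithelial factor ELF3 (-2.08 ± 0.25), SULF1 (-1.63 ± 0.19) and LAMP3 (-1.53 ± 0.13) had lower effects. RGS4 (1.26 ± 0.23) and the clock factor NPAS2 (1.302 ± 0.18) had higher effects and the retinal reductase DHRS3 a lower one (-1.35 ± 0.16).

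For this difference, of the integrated stress response list 16 of 30 had a higher effect in shTAZ cells and 0 a lower one (22 and 0 adjusted over the list alone; median log2 fold change 0.36). As a list, camera adjusted p = 8.21e-25 and adjusted p = 0.0368 with an estimated correlation. CHAC1 rose 6.02-fold in shCtrl and 15.8-fold in shTAZ cells (difference 1.39 ± 0.21), and SLC7A11 rose 5.01-fold and 11.7-fold (difference 1.23 ± 0.17). STC2 (1.05 ± 0.082) and SLC1A4 (0.91 ± 0.11) followed. Without shTAZ dabrafenib replicate 2, 10 stress response genes were called. Of ERK readouts 6 of 20 had a higher effect in shTAZ cells and 0 a lower one (13 and 0 adjusted over the list alone; median log2 fold change 0.50). Camera's adjusted p was 2.72e-15 with the preset correlation and adjusted p = 0.142 with an estimated correlation. ETV1 (1.11 ± 0.11), ETV5 (0.67 ± 0.10) and SPRED2 (0.61 ± 0.12) had higher effects, and without shTAZ vehicle replicate 1 the number was 13. Most ERK readouts were already lower in shTAZ vehicle cells, so for the list a lower start and a weaker response cannot be told apart. Mean SPRED2 went from 76.3 to 39.0 CPM in shCtrl and from 52.8 to 41.1 CPM in shTAZ cells. Mean ETV1 started alike, going from 41.4 to 5.35 CPM in shCtrl and from 39.98 to 11.1 CPM in shTAZ cells. Of YAP/TAZ targets 5 of 21 had a higher effect in shTAZ cells and 0 a lower one (7 and 0 adjusted over the list alone; median log2 fold change 0.16). Under camera adjusted p = 0.00171 was found, with adjusted p = 0.284 with an estimated correlation. CCN1 (0.67 ± 0.12) and NT5E (0.61 ± 0.090) had higher effects. Of lysosome genes 8 of 37 had a lower effect in shTAZ cells and 1 a higher one (17 and 2 adjusted over the list alone; median log2 fold change -0.20). Tested against other genes, the list had camera adjusted p = 1.63e-09, and adjusted p = 0.259 with an estimated correlation. The median was -0.13 without shTAZ dabrafenib replicate 4; ASAH1 (-0.76 ± 0.10) and LAMP1 (-0.47 ± 0.092) had lower effects. Of NRF2 genes 5 of 28 had a lower effect in shTAZ cells and 1 a higher one (8 and 2 adjusted over the list alone; median log2 fold change -0.092). In camera's comparison adjusted p = 5.05e-04, and adjusted p = 0.521 with an estimated correlation. AKR1C1 (-1.78 ± 0.20) and AKR1C3 (-1.67 ± 0.20), which share reads, had lower effects. The NRF2 median was -0.057 without shCtrl vehicle replicate 4, -0.055 without shTAZ vehicle replicate 2 and -0.031 without shTAZ dabrafenib replicate 4.

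The split of higher and lower effects, 412 and 509, was 457 and 459 with DESeq2's size factors, 549 and 393 when mitochondrial genes were left out, and 598 and 461 with a stricter filter on low counts. Without shTAZ dabrafenib replicate 4 it was 585 and 351, without shTAZ vehicle replicate 2 470 and 353, without shTAZ vehicle replicate 1 534 and 523, and without shCtrl vehicle replicate 4 425 and 393. The number of lower effects was 332 without shCtrl dabrafenib replicate 3, 327 without shCtrl dabrafenib replicate 4 and 338 without shTAZ vehicle replicate 4.

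**Figure D4:**
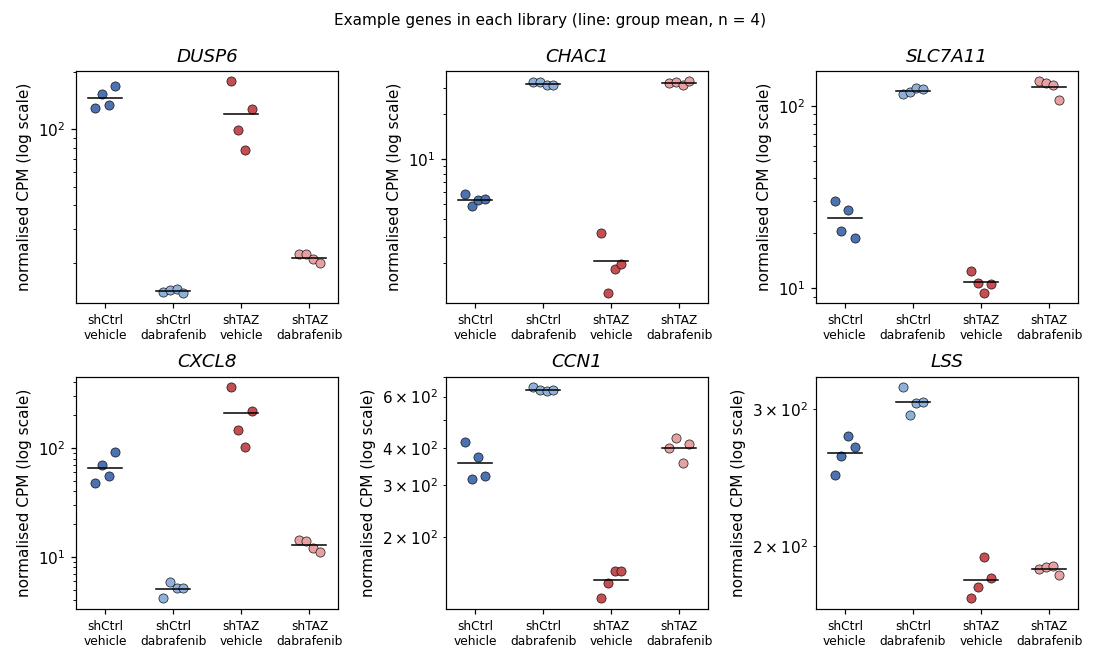
Normalised CPM (vertical axis, log scale) of DUSP6, CHAC1, SLC7A11, CXCL8, CCN1 and LSS in each library (points), with the group mean as a line (n = 4). CHAC1 rose from 5.35 ± 0.392 to 32.2 ± 0.847 CPM in shCtrl and from 2.07 ± 0.805 to 32.6 ± 0.801 CPM in shTAZ cells.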

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

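The tests chosen only after the result was seen were those of a lower starting level and of the mitochondrial share of counts, the fits with the mitochondrial percent as a covariate, the fits of the lists with libraries left out, and the margin described next. For 6 explanations, bounds had been set before their tests were run: excluded at 0.7 times the main value or more. The margin beyond that bound was 1 jackknife standard error over the left-out libraries, from fits without the covariate. It was chosen after the values were known. The bound alone would exclude 5 of the 6, a margin of 1 SD of the left-out values 3, and the jackknife margin used here 2. The cytokine test with the covariate, the interferon test with the covariate and the interferon test of single libraries are the ones that depend on this choice.

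Of stress response genes 16 of 30 rose more with dabrafenib in shTAZ than in shCtrl cells (median difference 0.36), and 10 without shTAZ dabrafenib replicate 2. With the log2 mitochondrial percent as a covariate the median was 0.37, above the bound of 0.25. It passed the bound by more than a jackknife error of 0.10 from fits without the covariate. The error of the median with the covariate was not computed. The share was also at least 4.03% in shTAZ and at most 3.66% in shCtrl dabrafenib libraries, which limits what the covariate can separate. Within these limits, the median argues against the mitochondrial share of the libraries as the whole cause. A lower starting level in shTAZ vehicle cells was not decided: the median shTAZ effect was -0.47 in vehicle and -0.089 under dabrafenib, where 10 members were lower and 3 higher; the latter median was -0.035 without shTAZ dabrafenib replicate 4. The median under dabrafenib met the prediction written for this explanation. Of the 30 members only 3 were called higher in shTAZ cells under dabrafenib, so for most the larger rise came without a called higher end level. These values go with a lower starting level. They do not decide, because a median near 0 over members that go both ways does not show equal levels. A lower level in vehicle is itself a difference between the hairpin lines, so it is no rival to an effect of the hairpin. For each gene the difference in dabrafenib effect is the shTAZ effect under dabrafenib minus that in vehicle. The median shTAZ effect was larger in size in vehicle than under dabrafenib. Whether the hairpin also changed the response to dabrafenib beyond the starting level stays open.

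Of cytokine genes 26 of 29, and of interferon genes 22 of 38, were higher in shTAZ than in shCtrl vehicle cells. Camera's call of the cytokine list was lost at adjusted p = 0.275 with an estimated correlation, and that of the interferon list at adjusted p = 0.622 with an estimated correlation. With the covariate the cytokine median was 0.96 (main 1.19, jackknife error of the main fit 0.30). The interferon median was 0.54 (main 0.63, error of the main fit 0.34). Both stayed above their bounds of 0.83 and 0.44, but by less than those errors, so a part played by the mitochondrial share cannot be told apart here. No single library carried the cytokine genes, since 23 members were still higher without shCtrl vehicle replicate 1, the lowest of 8 such fits. For interferon genes 16 were higher without shTAZ vehicle replicate 3, with a median of 0.33 against 0.63. Camera with the preset correlation still called the list there (adjusted p = 7.33e-04), but the spread over left-out libraries is wide, and with all libraries the call was already lost at adjusted p = 0.622 with an estimated correlation. How much of the change that library adds cannot be told apart, and an effect of the hairpin stays open.

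Of mitochondrial transcripts 4 of 13 were higher in shTAZ than in shCtrl cells under dabrafenib, and 0 with DESeq2. Camera gave adjusted p = 0.0146, and adjusted p = 0.740 with an estimated correlation. Without shTAZ dabrafenib replicate 4 the median was 0.78 against 1.45 (jackknife error 0.78), between the bounds, so what that library adds cannot be told apart. The mitochondrial share had a two-sided exact permutation p of 0.0286, and 0.114 adjusted over the 4 comparisons. The adjusted value was taken as the deciding one only after both were known. The unadjusted p, the smallest 4 against 4 libraries can give, would have excluded spread between cultures. With the other comparisons as they were, the adjusted p could not have been lower than 0.114. It therefore could not have excluded that spread, even though the share was higher in all 4 shTAZ than in all 4 shCtrl libraries. That spread and an effect of the hairpin therefore both stay open.

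For the number of genes called, other splits of the same libraries were fitted, with the real one included. For the dabrafenib effect in shCtrl cells, 1 of 35 splits gave as many genes: the real one called 7524 and the highest other 0. For the dabrafenib effect in shTAZ cells, 1 of 35 splits gave as many genes: the real one called 6950 and the highest other 116. For the shTAZ effect in vehicle, 1 of 35 splits gave as many genes: the real one called 6241 and the highest other 371. For the shTAZ effect in dabrafenib, 1 of 35 splits gave as many genes: the real one called 6593 and the highest other 0. For the difference in dabrafenib effect between shTAZ and shCtrl, 1 of 100 splits gave as many genes: the real one called 921 and the highest other 411. In each case only the real split gave as many genes, the smallest share that these splits can give. The other splits mixed libraries of both groups, so a real difference can widen their spread and lower their counts. For the difference, they also mixed the hairpin effect within each treatment, so they do not test the difference alone. The replicates may be technical, so chance differences between cultures are not excluded for any of the 5 counts.

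A library stood far from the other 3 of its group in 39 of 528 combinations of a group and a measure (a CPM or a quality value), where the gap to the nearest other library, as a share of the group's range, passed Dixon's 95% critical value. Chance marks about 1 in 20 groups, here 26.4. For shCtrl dabrafenib replicate 1 the gaps were NYNRIN 0.838 of the range. For shCtrl dabrafenib replicate 2 the gaps were KCNMB4 0.8291 of the range. For shCtrl dabrafenib replicate 3 the gaps were genes with counts 0.853, ROBO4 0.957 and KYNU 0.906 of the range. For shCtrl dabrafenib replicate 4 the gaps were PTGS2 0.922 of the range. For shCtrl vehicle replicate 1 the gaps were C3 0.896, LAMP3 0.865, MMP3 0.870, SCD 0.940 and HLA-B 0.938 of the range. For shCtrl vehicle replicate 2 the gaps were RGS4 0.902 of the range. For shCtrl vehicle replicate 3 the gaps were YAP1 0.869 and SQLE 0.896 of the range. For shCtrl vehicle replicate 4 the gaps were the share of the 50 most abundant genes 0.836 of the range. For shTAZ dabrafenib replicate 2 the gaps were SLC3A2 0.834 and IFI44 0.833 of the range. For shTAZ dabrafenib replicate 3 the gaps were OCLN 0.960 of the range. For shTAZ dabrafenib replicate 4 the gaps were the normalisation factor 0.8291, the mitochondrial percent 0.932, the share of the 50 most abundant genes 0.929, TAFAZZIN 0.846, ADM2 0.880, CXCL1 0.848 and COL27A1 0.843 of the range. In that library also COL7A1 0.892, SULF1 0.867, SLC4A4 0.860, AKR1C2 0.849, IL11 0.888, NKX2-1 0.921 and HLA-E 0.877. In that library also TNC 0.975, MT-CO1 0.906, MT-ND4 0.932 and CDH3 0.977. For shTAZ vehicle replicate 1 the gaps were ITGB2 0.854 and KCNMB4 0.960 of the range. For shTAZ vehicle replicate 2 the gaps were HMGCS1 0.924 of the range.

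The dabrafenib effect differed between shTAZ and shCtrl cells, by the interaction test of edgeR at adjusted p under 0.05, for 48 of the named genes. Log2 differences above 0, shTAZ minus shCtrl, were ADM2 1.47, CHAC1 1.39, CA9 1.14, RGS4 1.26, SLC7A11 1.23, JDP2 1.22, SLC1A4 0.91, LAMA4 1.71, SCG2 1.66 and HHIP 1.53. Further such differences were NPAS2 1.302, TGM2 1.24, ETV1 1.11, ETV4 0.79, ETV5 0.67, SPRED2 0.61, EPHA4 0.67, GADD45A 0.34, NT5E 0.61 and CCN1 0.67. Further such differences were CCN2 0.63, NUPR1 0.38, SESN2 0.32, STC2 1.05, VLDLR 0.31, MMP1 0.82, PLAT 0.70, IL24 0.67, MERTK 0.66 and TIE1 1.01. Further such differences were HERPUD1 0.30 and TNC 0.79. Log2 differences below 0 were SLPI -2.58, SULF1 -1.63, ITGB2 -0.80, SLC4A4 -0.80, FYB1 -2.21, ELF3 -2.08, AKR1C1 -1.78, AKR1C2 -1.86, AKR1C3 -1.67 and LAMP3 -1.53. Further such differences were DHRS3 -1.35, LAMP1 -0.47, ASAH1 -0.76, MCOLN1 -0.55, HLA-B -0.59 and CDH3 -1.07. Of these calls 42 held in each fit that left out 1 library and 6 did not, but list members were named mostly because their calls held, so this share is raised by that choice. Adjusted p values without the named library follow in brackets. For CCN2 the call was lost without shCtrl vehicle replicate 1 (0.0787), without shCtrl vehicle replicate 3 (0.0701), without shCtrl dabrafenib replicate 1 (0.0841), without shCtrl dabrafenib replicate 2 (0.0713), without shCtrl dabrafenib replicate 3 (0.0812), without shCtrl dabrafenib replicate 4 (0.0673), without shTAZ vehicle replicate 2 (0.0679), without shTAZ vehicle replicate 4 (0.0509), without shTAZ dabrafenib replicate 1 (0.0727) and without shTAZ dabrafenib replicate 2 (0.0958). For MERTK the call was lost without shCtrl vehicle replicate 1 (0.0520), without shCtrl dabrafenib replicate 1 (0.0556), without shCtrl dabrafenib replicate 4 (0.0659), without shTAZ vehicle replicate 3 (0.0519), without shTAZ vehicle replicate 4 (0.0569) and without shTAZ dabrafenib replicate 2 (0.0677). For NUPR1 the call was lost without shCtrl vehicle replicate 3 (0.0597), without shCtrl dabrafenib replicate 2 (0.0690), without shCtrl dabrafenib replicate 3 (0.0630), without shCtrl dabrafenib replicate 4 (0.0681), without shTAZ vehicle replicate 3 (0.0540), without shTAZ vehicle replicate 4 (0.0668), without shTAZ dabrafenib replicate 1 (0.0685) and without shTAZ dabrafenib replicate 2 (0.0701). For SESN2 the call was lost without shCtrl vehicle replicate 1 (0.0579), without shCtrl vehicle replicate 3 (0.0623), without shCtrl dabrafenib replicate 1 (0.0582), without shCtrl dabrafenib replicate 3 (0.0655), without shCtrl dabrafenib replicate 4 (0.0663), without shTAZ vehicle replicate 4 (0.0730), without shTAZ dabrafenib replicate 2 (0.0712) and without shTAZ dabrafenib replicate 3 (0.0511). For SLC4A4 the call was lost without shCtrl vehicle replicate 2 (0.0708), without shCtrl vehicle replicate 4 (0.0675), without shCtrl dabrafenib replicate 3 (0.0718), without shCtrl dabrafenib replicate 4 (0.0691), without shTAZ vehicle replicate 2 (0.0866), without shTAZ vehicle replicate 3 (0.0677), without shTAZ vehicle replicate 4 (0.0537), without shTAZ dabrafenib replicate 1 (0.0530) and without shTAZ dabrafenib replicate 4 (0.0654). For VLDLR the call was lost without shCtrl vehicle replicate 2 (0.0544), without shCtrl vehicle replicate 3 (0.0623), without shCtrl dabrafenib replicate 1 (0.0518), without shCtrl dabrafenib replicate 2 (0.0620), without shCtrl dabrafenib replicate 3 (0.0522), without shTAZ dabrafenib replicate 1 (0.0559) and without shTAZ dabrafenib replicate 2 (0.0677).

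Camera with the preset correlation called a difference in dabrafenib effect for these lists, given with the median log2 difference, shTAZ minus shCtrl. Only the integrated stress response kept its call with an estimated correlation. A called list can hold few called members: G1/S and replication had 0 higher and 0 lower, and mitosis 1 higher and 0 lower. Medians were ERK readouts 0.50, YAP/TAZ targets 0.16, G1/S and replication -0.12, mitosis 0.17, receptor tyrosine kinases 0.062 and cholesterol synthesis -0.15. Others were integrated stress response 0.36, epithelial genes -0.13, matrix proteases 0.094, interferon genes -0.40, antigen presentation -0.15 and cytokines -0.33. Others were NRF2 and ferroptosis -0.092, ribosome biogenesis -0.074, lysosome and autophagy -0.20, fibroblast markers -0.41 and neural markers 0.79. Camera's adjusted p rose above 0.05 when 1 library was left out for some of them, given in brackets. For G1/S and replication this was without shCtrl vehicle replicate 4 (0.268) and without shTAZ vehicle replicate 2 (0.271). For cytokines this was without shCtrl vehicle replicate 1 (0.159), without shCtrl vehicle replicate 3 (0.0718) and without shTAZ vehicle replicate 1 (0.266). For antigen presentation this was without shTAZ vehicle replicate 3 (0.0646) and without shTAZ dabrafenib replicate 4 (0.0638). For matrix proteases this was without shCtrl vehicle replicate 3 (0.0727), without shCtrl vehicle replicate 4 (0.0506) and without shTAZ dabrafenib replicate 2 (0.0640). For neural markers this was without shCtrl vehicle replicate 4 (0.0618), without shTAZ vehicle replicate 1 (0.0824) and without shTAZ vehicle replicate 2 (0.0676). For ribosome biogenesis this was without shCtrl vehicle replicate 4 (0.213), without shCtrl dabrafenib replicate 1 (0.0576), without shTAZ vehicle replicate 1 (0.242), without shTAZ vehicle replicate 2 (0.272) and without shTAZ dabrafenib replicate 4 (0.0621). For interferon genes this was without shTAZ vehicle replicate 3 (0.314). The median moved by over 1.5 times, with the call kept, in these fits. For mitosis it was 0.089 without shCtrl vehicle replicate 1, 0.26 without shCtrl vehicle replicate 4, 0.093 without shTAZ vehicle replicate 1 and 0.26 without shTAZ vehicle replicate 2. For NRF2 and ferroptosis it was -0.057 without shCtrl vehicle replicate 4, -0.055 without shTAZ vehicle replicate 2 and -0.031 without shTAZ dabrafenib replicate 4. For receptor tyrosine kinases it was 0.15 without shCtrl vehicle replicate 1, 0.10 without shCtrl vehicle replicate 2, 0.15 without shCtrl dabrafenib replicate 1, 0.11 without shCtrl dabrafenib replicate 3, 0.10 without shTAZ vehicle replicate 1, 0.12 without shTAZ dabrafenib replicate 1, 0.14 without shTAZ dabrafenib replicate 2, 0.11 without shTAZ dabrafenib replicate 3 and 0.12 without shTAZ dabrafenib replicate 4. For cholesterol synthesis it was -0.061 without shTAZ dabrafenib replicate 4. For epithelial genes it was -0.25 without shCtrl vehicle replicate 1, -0.19 without shCtrl vehicle replicate 4, -0.26 without shTAZ vehicle replicate 1 and -0.25 without shTAZ vehicle replicate 4. For matrix proteases it was 0.15 without shCtrl vehicle replicate 1, 0.013 without shCtrl dabrafenib replicate 1, -0.0079 without shTAZ vehicle replicate 3, 0.062 without shTAZ vehicle replicate 4, 0.030 without shTAZ dabrafenib replicate 1 and 0.15 without shTAZ dabrafenib replicate 4. For fibroblast markers it was -0.62 without shCtrl vehicle replicate 3 and -0.26 without shTAZ vehicle replicate 3. For lysosome and autophagy it was -0.13 without shTAZ dabrafenib replicate 4. For ribosome biogenesis it was -0.12 without shTAZ vehicle replicate 3. With an estimated correlation 1 list, the integrated stress response, was called (adjusted p = 0.0368).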

How the results depend on the processing

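The fits with the mitochondrial percent as a covariate, without mitochondrial genes, and of the lists with libraries left out were chosen only after the data were seen. The counts of genes called stayed within 1.5 times under the other settings, except for the difference in dabrafenib effect. There 653 genes had higher and 785 lower effects with the covariate, and DESeq2 called 700 higher; the cause was not tested. With an estimated correlation camera called 4, 6, 3, 1 and 1 lists in the 5 comparisons, in the order of the report, and fry called 8 for the difference. Camera with an estimated correlation takes the correlation between genes from the data, and the other lists lost their calls under it. What part of that loss comes from the correlation alone was not tested. Fry tests each list by itself.

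The correlation of the dabrafenib effects was 0.211 with no filter on low counts, 0.851 with a stricter one and 0.804 with only the groups compared in each fit (jackknife SE 0.0251). That of the shTAZ effects was 0.142, 0.760 and 0.720 (jackknife SE 0.0410). The cause was not tested. The mitochondrial list under dabrafenib turned to an adjusted p of 0.425 in the other direction with the covariate, and MT-CO1 under dabrafenib to -9.81e-04 log2 and MT-ND4 in vehicle to -0.19 log2, which follows from the construction, since the covariate is made from these genes.

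Leaving out 1 library at a time gave these ranges. For the dabrafenib effect in shCtrl cells, genes higher ranged 3338 to 3953, lower 3107 to 3592 and lists called 19 to 21. For the dabrafenib effect in shTAZ cells, genes higher ranged 3065 to 3675, lower 3035 to 3376 and lists called 19 to 20. For the shTAZ effect in vehicle, genes higher ranged 2323 to 2864, lower 3054 to 3422 and lists called 16 to 19. For the shTAZ effect in dabrafenib, genes higher ranged 2261 to 2741, lower 2995 to 3577 and lists called 17 to 21. For the difference in dabrafenib effect between shTAZ and shCtrl, genes higher ranged 298 to 585, lower 327 to 523 and lists called 14 to 18. The correlations ranged 0.711 to 0.732 and 0.591 to 0.641. Each set an effect from the fit without the library against the other effect from the fit with all libraries. The first range lies wholly below the value of 0.735 with all libraries, and the cause was not tested. Of 472 called pairs of a named gene and a comparison, leave-one-out fits kept 4045 of 4160 values and the other settings 4166 of 4198, with 1 change of sign in all. List members were named mostly because their calls held with libraries left out, so these shares are raised by that choice.

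With the replicate number as a replicate block, 4062 genes were higher and 3495 lower for the dabrafenib effect in shCtrl cells, 3522 genes were higher and 3480 lower for the dabrafenib effect in shTAZ cells, 2929 genes were higher and 3479 lower for the shTAZ effect in vehicle, 2871 genes were higher and 3749 lower for the shTAZ effect in dabrafenib and 407 genes were higher and 479 lower for the difference in dabrafenib effect between shTAZ and shCtrl. The numbers were not stated to pair libraries: 2 of 24 same-number pairs had a correlation of deviations above 0.1 (range -0.10 to 0.32), and 5 of 16 libraries correlated best with their own number. Counts below about 10 per library limit the genes near the filter.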

Other observations

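The tests of lists with libraries left out, and which lists to describe, were chosen only after the result was seen; the lists were fixed before the data were examined. Genes of the actin cytoskeleton rose with dabrafenib, where in shCtrl cells 15 of 25 rose and 3 fell (15 and 3 adjusted over the list alone; median log2 fold change 0.29). The list test (camera) had adjusted p = 5.25e-04, or adjusted p = 0.358 with an estimated correlation. In shTAZ cells 16 of 25 rose and 3 fell (17 and 3 adjusted over the list alone; median log2 fold change 0.36). By camera the adjusted p was 3.44e-06, and adjusted p = 0.223 with an estimated correlation. TPM1 (0.88 ± 0.051 and 0.70 ± 0.051), LIMA1 (0.68 ± 0.048 and 0.90 ± 0.048) and ACTG1 (0.64 ± 0.051 and 0.80 ± 0.051) rose in shCtrl and shTAZ cells. Mesenchymal genes fell as a list in shCtrl cells, where 17 of 32 fell and 7 rose (17 and 8 adjusted over the list alone; median log2 fold change -0.46). For the list, camera's adjusted p = 0.00220, against adjusted p = 0.479 with an estimated correlation. TNC, a matrix glycoprotein, fell (-1.62 ± 0.11). In shTAZ cells, of mesenchymal genes 16 of 32 fell and 5 rose (17 and 6 adjusted over the list alone; median log2 fold change -0.34). Against other genes, camera gave adjusted p = 0.00216, and adjusted p = 0.479 with an estimated correlation. Replication-dependent histone genes, which poly(A) libraries hold at low levels, fell too: in shCtrl cells 15 of 19 fell and 0 rose (16 and 0 adjusted over the list alone; median log2 fold change -0.80). As a list, camera adjusted p = 3.75e-04 and adjusted p = 0.468 with an estimated correlation. In shTAZ cells 11 of 19 fell and 0 rose (13 and 0 adjusted over the list alone; median log2 fold change -0.50). Camera's adjusted p was 0.00469 with the preset correlation and adjusted p = 0.576 with an estimated correlation. Of the thyroid differentiation list 4 of 8 rose and 2 fell (4 and 2 adjusted over the list alone) in shCtrl cells, with no camera call (adjusted p = 0.269). DIO2, which activates thyroid hormone, rose (2.63 ± 0.26), NKX2-1 rose (0.50 ± 0.090) and PAX8 fell (-0.85 ± 0.21), the latter being thyroid transcription factors.

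The TAZ hairpin came with lower chaperone and folding genes, where in vehicle 15 of 20 were lower and 1 was higher (17 and 1 adjusted over the list alone; median log2 fold change -0.29). Under camera adjusted p = 3.39e-06 was found, with adjusted p = 0.284 with an estimated correlation. Under dabrafenib 16 of 20 were lower and 0 were higher (16 and 0 adjusted over the list alone; median log2 fold change -0.31). Tested against other genes, the list had camera adjusted p = 4.82e-06, and adjusted p = 0.284 with an estimated correlation. HERPUD1 was lower in both (-0.66 ± 0.051 and -0.36 ± 0.050). Of fatty acid synthesis genes under dabrafenib 10 of 15 were lower and 3 were higher (11 and 3 adjusted over the list alone; median log2 fold change -0.29). In camera's comparison adjusted p = 1.35e-04, and adjusted p = 0.284 with an estimated correlation. Epithelial genes were lower under dabrafenib, where 17 of 23 were lower and 1 was higher (17 and 2 adjusted over the list alone; median log2 fold change -0.45). Camera gave adjusted p = 5.64e-04 for the list, and adjusted p = 0.227 with an estimated correlation. OCLN (-1.02 ± 0.12) and CDH3 (-1.85 ± 0.18) were lower. Antigen presentation genes were lower under dabrafenib, where 16 of 24 were lower and 3 were higher (17 and 3 adjusted over the list alone; median log2 fold change -0.28). The list test (camera) had adjusted p = 0.00222, or adjusted p = 0.576 with an estimated correlation. HLA-E (-0.67 ± 0.069) and HLA-B (-0.67 ± 0.10) were lower. The lists of BCL2 family, TGF-beta and BMP targets, Notch and Wnt targets and thyroid differentiation had no camera call in any of the 5 comparisons. Neither did growth factor ligands, apart from the dabrafenib effect in shTAZ cells without shTAZ vehicle replicate 3 (adjusted p = 0.0486), and oxidative phosphorylation with all libraries. The latter was called for the shTAZ effect in dabrafenib, where the adjusted p was 0.0744 with all libraries, without shCtrl dabrafenib replicate 2 (0.0458), 3 (0.0387) or 4 (0.0447) or shTAZ dabrafenib replicate 1 (0.0123) or 3 (0.0391). It was also called for the dabrafenib effect in shCtrl cells without shCtrl vehicle replicate 1 (0.0246), that in shTAZ cells without shTAZ dabrafenib replicate 4 (0.0114) and the shTAZ effect in vehicle without shCtrl vehicle replicate 4 (0.0488).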
